A study of Mus musculus with 30 samples.

How the data were processed

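Mouse T cells from thymus or spleen were enriched for CD4 cells, sorted by flow cytometry and sequenced as 30 libraries made with a stranded mRNA kit, per the labels. The deposited files hold raw read counts per gene, which the authors made with 1 file per library and no normalization. Per the submitters' processing notes, reads were processed with STAR and HTSeq on the mm9 genome; versions are not given. The strand setting of the counting is not given in the sources used here, so reads of overlapping or antisense genes may have been assigned to either. Each file lists versioned Ensembl genes and 5 summary lines of reads that were not assigned. The summary lines were left out; they held 17.5% to 33.1% of the counts in a file, with 11.0% to 26.0% assigned to no feature. Gene symbols and positions came from the matching GENCODE annotation, to which all genes mapped.

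Groups followed the labels on tissue, sorted cell type and genotype, and replicate numbers came from the sample titles. All 30 libraries were used. Within each group every pair of replicates was checked for copies: no pair lay within sampling noise, with chi-square per degree of freedom from 2.52 to 14.54. The highest values, 14.54 and 10.8, were those of spleen Tcon replicate 2 with its mates, against 3.27 for the other Tcon pair, and this library also had the 26.0% assigned to no feature. Depth ran from 3065421 to 9504930 counts in genes per library, which limits what could be seen for genes of a few CPM.

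Counts were fitted with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr by group (minimum count 10, minimum total 15), dispersions by estimateDisp and a robust quasi-likelihood F test. Several groups had only 2 libraries, so related groups were fitted together to share an estimate of the spread. The 4 fits held 14 thymocyte libraries (12419 genes kept, biological coefficient of variation 0.101), 10 Foxp3-allele libraries (12405 genes, 0.093), 6 spleen libraries (10694 genes, 0.105) and 10 libraries of spleen and thymic Treg and conventional cells (11645 genes, 0.098). The 13 results were 11 contrasts between groups and 2 differences of contrasts. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and SE is the size of the log2 fold change over the square root of F. Levels are CPM of counts in genes. In a contrast of 2 groups a gene with no counts in a group was given a bound from 3 counts over that group, while differences of contrasts are fitted values. The choices of fits, contrasts, gene lists, alternatives and named genes were fixed before the data were examined, except where stated.

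The genes named per comparison were the 6 largest rises and 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between libraries, passing over unnamed and predicted genes and antigen-receptor segments. Added to these were 2 to 4 members with the lowest adjusted p of each list discussed, and Foxp3, Il2ra, Cd4 and Cd8a. For the differences of contrasts the overlap condition was dropped.

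In total 24 gene lists were fixed: Treg-associated genes, genes that Treg cells reduce, TCR signalling, NF-kB and tumour necrosis factor receptors, interleukin-2 and STAT5, helper cytokines and effectors, thymic egress and maturation, immature thymocytes, early CD4-CD8- cells, CD4+CD8+ thymocytes, CD4 lineage, CD8 lineage, proliferation, interferon response, chromatin architecture, T-cell transcription factors, B cells, myeloid cells, dendritic cells, natural killer and gamma-delta T cells, thymic epithelium, erythroid cells, dissociation stress and sex-linked genes. They were tested with fry and camera of limma 3.58.1 on log CPM, camera with a preset correlation of 0.01 and again with an estimated one. Of 288 list tests, 154 passed by camera with the preset correlation and 68 of them with an estimated one. fry tests whether a list's genes move one way on balance, and it compares them with no other genes. Genes at least 2-fold different between spleen Treg and Tcon cells were used as further sets. The overlap of the Foxp3-allele contrasts was tested by Fisher's exact test, 2-sided, over the genes of their common fit.

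The scripts were tested on simulated counts with known changes. The counts were drawn from each gene's mean over all libraries of a fit and the fitted dispersions. At each fold size 58 to 70 of the genes kept were changed, and the shares recovered hold for that setting. For 2-fold changes edgeR recovered 65.2% in the thymic Treg contrast (11936 genes kept), 88.4% in spleen (10537), 72.5% for the knockout (12092), 72.9% for the DSM mutant (12081), 62.1% for their difference (12077) and 50.7% for the difference of spleen and thymus (11283). For 1.5-fold changes the shares were 41.5%, 59.4%, 49.3%, 52.9%, 25.8% and 22.7%, and 5 to 8 unchanged genes were called in each.

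Alternatives were RLE factors, no filter and a stricter filter on low counts (5 CPM), a replicate block, DESeq2 1.42.0, a threshold of at least 2-fold, each replicate left out in turn, all 30 libraries in 1 fit and only the groups compared. Fits without the CD25+ reporter-negative and CD8 libraries, and a spleen and thymus difference with the CD25- reporter-positive group, were added after seeing the data. Where leaving out a library left 1 in a group, that library was taken to vary like the others of its fit. No contrast was made between libraries labelled CD8 and other mature CD8 cells, since none were deposited.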

Results

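Polyadenylated RNA was measured by stranded sequencing in 30 libraries of sorted mouse T cells, 24 from thymus and 6 from spleen, in 13 groups. The series title places the libraries in a study of Foxp3, the transcription factor that defines regulatory T (Treg) cells, and of chromatin architecture. From thymus there were 2 libraries each of CD4-CD8- cells, CD4+CD8+ cells, CD8 single-positive cells and 4 gates of CD4 single-positive cells set by CD25 and a Foxp3 reporter. The gates were CD25- reporter-negative (called conventional CD4 below), CD25+ reporter-negative, CD25- reporter-positive and CD25+ reporter-low. Treg cells of 4 Foxp3 genotypes, also labelled thymus, comprised 3 libraries with a domain-swap mutant (DSM), 3 DSM wild-type libraries, 2 Foxp3 knockout libraries and 2 wild-type libraries with a green fluorescent protein (GFP) reporter. From spleen there were 3 libraries of Treg and 3 of conventional T (Tcon) cells.

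The libraries held 3065421 to 9504930 counts in genes. The CD4 gates ranged from 3418695 to 5180975 counts, CD4-CD8-, CD4+CD8+ and CD8 libraries from 3065421 to 4640311, the DSM mutant from 5010362 to 9504930 and its wild type from 6660260 to 7455572. The GFP wild type held 8713479 and 6044605 counts and the knockout 4589551 and 4592700, while spleen Treg libraries ranged from 4095134 to 6553812 and spleen Tcon from 4311486 to 5636971. Between 13955 and 16101 genes had a count, and the most abundant gene took 0.81% to 1.59% of a library. Levels below are in CPM, counts scaled to the library total, as group means. Fold changes are on the log2 scale with their standard error (SE) after ±, and adjusted p values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. For each gene list the count adjusted over the list alone is given where it differs from the count over all genes. Where a group had no count of a gene, a fold given as at least a value is a lower bound set by 3 counts over that group, and bounds and errors cover counting and the spread between libraries only. The labels do not say that replicates came from separate animals, so the p values measure only the spread between these samples, which may be technical.

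Gate markers were read first. Foxp3 (ENSMUSG00000039521.5, mm9 chromosome X, 7156802 to 7172369) stood at 883 and 896 CPM in the CD25+ reporter-low libraries and at 788 and 801 CPM in the CD25- reporter-positive ones, so the gate labelled reporter-low was not shown to have less Foxp3 transcript, and a difference between the 2 gates was not called (adjusted p = 0.42). Il2ra, which encodes CD25 (ENSMUSG00000026770.4, chromosome 2, 11564419 to 11614818), was at 455 CPM in both libraries labelled CD25- reporter-positive, against 13.4 and 10.8 CPM in conventional CD4 cells. In the CD25+ reporter-negative libraries Foxp3 was present at 67.9 and 58.2 CPM. Cd4 (ENSMUSG00000023274.7, chromosome 6, 124814710 to 124838239) averaged 710 to 1500 CPM in the 4 CD4 gates, 951 CPM in CD4+CD8+ cells and 46.7 CPM in the CD8 libraries. Cd8a (ENSMUSG00000053977.7, chromosome 6, 71323421 to 71329165) averaged 926 CPM in CD4+CD8+ cells and 486 CPM in the CD8 libraries. Rag1, needed to build the TCR, had 4 counts in the 10 Foxp3-allele libraries labelled thymus and 158 in the 4 thymic libraries of the reporter-positive and reporter-low gates.

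**Figure D1:**
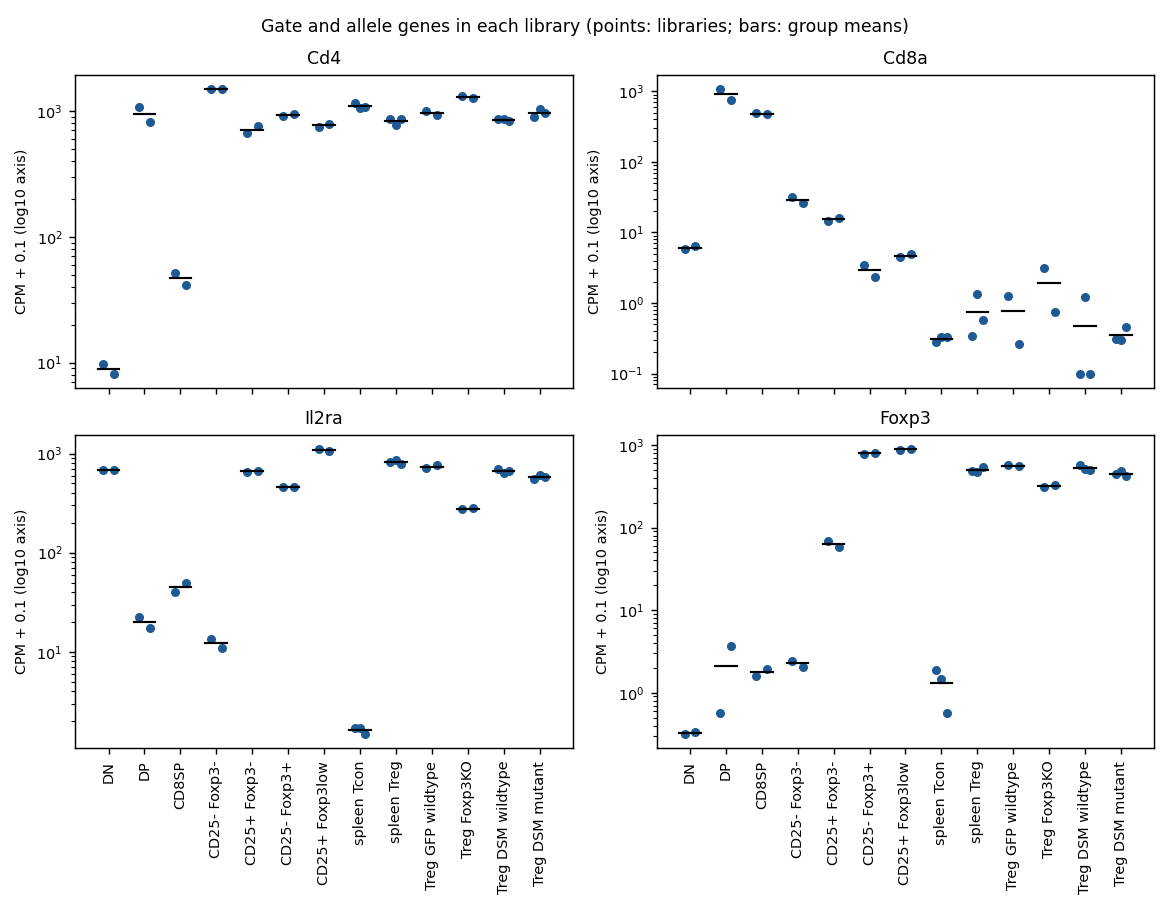
Level of Cd4, Cd8a, Il2ra and Foxp3 in each of the 30 libraries, by group, in CPM plus 0.1 on a log10 axis; each point is 1 library and each bar is the group mean. Il2ra was at 455 CPM in both CD25- reporter-positive libraries, and Foxp3 was detected in every knockout library (309 and 329 CPM).

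The step from CD4-CD8- to CD4+CD8+ cells asks which genes change as thymocytes pass the pre-T-cell-receptor checkpoint and take on both coreceptors. Cd8a rose by 7.33 ± 0.18 and Cd4 by 6.80 ± 0.16 (n = 2 per group, 926 against 5.95 CPM and 951 against 8.84 CPM). Il2ra fell from 689 to 19.8 CPM, a log2 fold change of -5.05 ± 0.13 (adjusted p = 1.24e-30 by edgeR). Rorc, whose product prolongs the survival of CD4+CD8+ cells, rose from 60.7 to 525 CPM (3.17 ± 0.14), and Bcl6 from 13.0 to 178 CPM (3.83 ± 0.20). Notch1, the receptor that drives early T-cell commitment, fell by 1.55 ± 0.10, and its target Hes1 fell from 48.4 to 2.47 CPM. In all, 4133 of 12419 genes passed, 2052 higher and 2081 lower in CD4+CD8+ cells.

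Of 16 CD4+CD8+ thymocyte genes, 13 were higher, none lower and 3 not called (14 higher and none lower adjusted over the list alone), among them Satb1 (2.29 ± 0.09) and Cd8b1 (4.61 ± 0.15). Among 19 genes of early CD4-CD8- cells, 12 were lower, 1 higher and 6 not called, among them Il7r (-1.86 ± 0.15). Genes of T-cell-receptor (TCR) signalling went up more than down: 12 of 22 were higher and 3 lower (14 and 4 adjusted over the list alone), with Cd5 at 392 against 42.4 CPM, Nr4a3 up by 3.24 ± 0.20 and Myc at -1.44 ± 0.11. That list's camera call was lost, at an adjusted p = 0.157 with an estimated correlation. All 7 natural killer and gamma-delta T-cell genes were lower, including Sox13 at 3.93 against 149 CPM. The proliferation list had 16 higher and 4 lower of 25 (16 and 6 adjusted over the list alone; Mki67 0.72 ± 0.10; adjusted p = 0.41 with an estimated correlation), and of 16 chromatin architecture genes 7 were higher and none lower (Rad21 0.85 ± 0.10, Ctcf 0.64 ± 0.10; adjusted p = 0.208 with an estimated correlation). Of 8 dendritic-cell genes 1 was higher and 2 lower, with a median below 0, a mean above 0 and a camera direction below 0. Genes of neutrophils were among the largest falls, with S100a8 at 0 against 68.1 CPM, at least 164-fold lower, and Ngp at least 352-fold lower. Of 12 B-cell genes 9 were lower and 1 higher (9 and 2 adjusted over the list alone; Cd19 at 15.4 against 54.9 CPM; adjusted p = 0.327 with an estimated correlation), and Epcam, an epithelial gene, was at 4.29 against 33.3 CPM. Of 13 myeloid genes 5 were lower and 1 higher (adjusted p = 0.274 with an estimated correlation), and of 4 thymic epithelial genes 3 were lower.

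Conventional CD4 cells against CD4+CD8+ cells address positive selection into the CD4 lineage and exit from the cell cycle. Zbtb7b, the regulator that commits cells to the CD4 lineage, rose from 10.5 to 594 CPM (5.87 ± 0.17, n = 2 per group), while Cd8a fell from 926 to 29.1 CPM (-4.94 ± 0.15, adjusted p = 9.72e-27 by edgeR). S1pr1, the receptor for leaving the thymus, rose from 3.12 to 195 CPM (5.98 ± 0.20), and the homing receptor Ccr7 from 22.2 to 316 CPM (3.90 ± 0.15). All 25 proliferation genes were lower, among them Mki67 (-2.74 ± 0.11), Rrm2 (-3.19 ± 0.14) and Mcm6 (-2.14 ± 0.10). Rag2, which cuts TCR gene segments, fell from 150 to 4.46 CPM, Rorc fell by 4.82 ± 0.16 and Arpp21 fell by 4.85 ± 0.14. In total 5176 of 12419 genes passed, 2517 higher and 2659 lower, with Foxp3 not called (2.16 against 2.03 CPM, 0.32 ± 0.51, adjusted p = 0.664). The Foxp3 value was -0.66 without CD4+CD8+ replicate 1 and 2.16 (adjusted p = 0.0354) without replicate 2.

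Of 14 genes of egress and maturation, 13 were higher and 1 lower, including Il7r (3.58 ± 0.15) and Itgb7 (3.60 log2). The CD4-lineage list had 7 higher and 1 lower of 8, with Cd40lg up by 2.76 and Myb at -3.20 ± 0.11. Among 12 genes of immature thymocytes 8 were lower and 3 higher. Interferon-response genes were higher in 20 of 22 cases and lower in none, with Stat1 at 684 against 173 CPM and Oas2 at 136 against 8.06 CPM. Of 14 genes of NF-kB and tumour necrosis factor receptors, 12 were higher and 1 lower (Tnfrsf4 4.27 ± 0.23, Tnfrsf18 2.48; adjusted p = 0.0631 with an estimated correlation). Of 16 chromatin architecture genes, 10 were lower and 2 higher, among them Rad21 (-1.29 ± 0.10) and Ctcf (-0.81 ± 0.10), with an adjusted p = 0.162 with an estimated correlation. The largest rises from no counts were at least 18.1-fold for Akr1c18, 16.4-fold for Apol9a and 13.1-fold for Adh1, and Igfbp4 rose by 6.13 ± 0.21. Falls to no counts were at least 49.8-fold for AB069917, 19.8-fold for Nrg2, 18.6-fold for Siglecg and 14.8-fold for Degs2. Antigen-presenting-cell genes were among those lower, with H2-Ab1 at 5.35 against 86.3 CPM and Cd79b at 0.598 against 14.4 CPM; 10 of 12 B-cell genes (adjusted p = 0.132 with an estimated correlation) and all 8 dendritic-cell genes (0.0824 likewise) were lower.

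CD8 libraries against conventional CD4 cells compare the gates labelled CD8 and CD4 single-positive. They may not show the CD4 and CD8 lineage choice, since the CD8 libraries may hold cells from before it. Zbtb7b stood at 0.691 against 594 CPM (-9.59 ± 0.25, n = 2 per group, adjusted p = 1.82e-28 by edgeR), Cd4 at 46.7 against 1500 CPM (-5.02 ± 0.13) and Cd8a at 486 against 29.1 CPM (4.03 ± 0.15). Genes of dividing cells were abundant in the libraries labelled CD8. Mki67 was at 2360 against 287 CPM (3.01 ± 0.11), Mcm6 at 927 against 115 CPM (2.98 ± 0.11), and all 25 proliferation genes were higher. Rorc was at 158 against 17.9 CPM, Ptcra, the pre-TCR alpha chain, at 41.3 against 1.43 CPM and Arpp21 at 400 against 17.8 CPM. Maturation genes ran the other way, with Ccr7 at 31.0 against 316 CPM (-3.37 ± 0.14) and Il7r at -3.27 ± 0.14; of 14 egress and maturation genes 13 were lower and 1 higher.

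The count of genes passing was 7195 of 12419, with 3619 higher and 3576 lower in CD8 libraries. Of 14 CD8-lineage genes 7 were higher, 4 lower and 3 not called (camera adjusted p = 0.102), with Gzma at 149 against 2.26 CPM and Itgae up by 2.04 ± 0.17. The CD4-lineage list had 7 lower and 1 higher of 8. TCR-signalling genes were lower in 16 of 22 cases and higher in 1, among them Cd5 (-2.95 ± 0.12) and Egr2 (-3.68 log2), with an adjusted p = 0.113 with an estimated correlation. Interferon-response genes were lower in 20 of 22 and higher in none (Stat1 -2.05 ± 0.10; adjusted p = 0.113 with an estimated correlation). Of 16 chromatin architecture genes 11 were higher and 3 lower (Trim28 1.36 ± 0.10, Rad21 1.29 ± 0.10; adjusted p = 0.225 with an estimated correlation). Asb2 was at 0 against 36.7 CPM, at least 96.8-fold lower, Mapk12 at least 21.9-fold and Mmp9 at least 21.6-fold lower, while Nrg2 was at least 28.0-fold and Cpa3 at least 22.8-fold higher. Gfra1 rose by 6.85 ± 0.34. Of 12 B-cell genes 8 were higher and none lower (Ighm at 1010 against 126 CPM, Igkc at 330 against 2.77 CPM; adjusted p = 0.375 with an estimated correlation). Of 8 dendritic-cell genes 7 were higher and none lower (8 higher adjusted over the list alone; H2-Ab1 at 59.3 against 5.35 CPM; adjusted p = 0.198 with an estimated correlation).

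CD25+ reporter-negative cells against conventional CD4 cells ask what marks the candidate Treg precursor that carries CD25 before the Foxp3 reporter. They may not show the precursor alone, since CD25+ CD4-CD8- cells mixed in could not be told apart from a change particular to this gate. Il2ra was at 661 against 12.1 CPM (5.62 ± 0.14, n = 2 per group, adjusted p = 1.59e-31 by edgeR) and Foxp3 at 63.0 against 2.16 CPM (4.70 ± 0.25). Penk and Ctla4, both Treg-associated, rose by 4.29 ± 0.24 and 2.32 ± 0.15, and Tnfrsf9, a costimulatory receptor induced by TCR signals, by 1.79 ± 0.14. Some genes of less mature thymocytes were higher as well, with Ptcra at 65.0 against 1.43 CPM (5.32 ± 0.31), Notch1 at 1050 against 326 CPM (1.54 ± 0.10), Rag2 at 43.3 against 4.46 CPM and Arpp21 at 305 against 17.8 CPM. The genes passing numbered 4344 of 12419, 2188 higher and 2156 lower, and of those that differed at least 2-fold 1167 were higher and 597 lower.

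Treg-associated genes were split, with 20 of 34 higher, 7 lower and 7 not called (21 higher and 8 lower adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). Of 18 genes that Treg cells reduce, 14 were lower and none higher, including Satb1 (-1.46 ± 0.08), Igfbp4 (-2.73 ± 0.15) and Lef1 (-1.41 ± 0.10). The early CD4-CD8- list had 10 higher and 3 lower of 19 (11 and 3 adjusted over the list alone). The immature-thymocyte list had 6 higher and 4 lower of 12 (camera adjusted p = 0.0801). Of 25 proliferation genes 22 were higher and none lower (25 and none adjusted over the list alone), with Mcm6 at 427 against 115 CPM and an adjusted p = 0.13 with an estimated correlation. Interferon-response genes were lower in 16 of 22 and higher in none (adjusted p = 0.188 with an estimated correlation). CD4+CD8+ thymocyte genes divided evenly, 6 higher and 6 lower of 16 (7 and 6 adjusted over the list alone), with a median below 0 and a mean above 0. Zbtb7b fell to 194 from 594 CPM (-1.75 ± 0.12) and Cd4 fell by 1.22 ± 0.10, while Myb rose by 2.56. Mpzl2 was at 38.3 CPM, at least 106-fold higher, Khdc1a at least 92.6-fold, Cpa3 at least 53.8-fold, Clec12a at least 34.8-fold and Sstr2 at least 25.3-fold higher. The largest falls were Cntnap1 (-4.38 ± 0.66), Cyp2s1 (-3.77 ± 0.73), Klrb1c (-3.31 ± 0.55), Fasl (-3.07 ± 0.76) and Vipr1 (15.6 against 118 CPM). The epithelial marker Epcam was at 25 against 1.08 CPM and Cd79b, of the B-cell list, at 10.5 against 0.598 CPM. Cd19, another B-cell gene, was at 1.46 and 0.835 CPM against 0.938 and 0.492 CPM, so Cd79b by itself does not show B cells.

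CD25- reporter-positive cells against conventional CD4 cells ask what marks the Foxp3-expressing cells that were sorted as CD25-negative. Foxp3 was at 794 against 2.16 CPM (8.50 ± 0.20, n = 2 per group, adjusted p = 5.48e-32 by edgeR) and Il2ra at 455 against 12.1 CPM (5.23 ± 0.14). Ctla4, an inhibitory receptor of Treg cells, was at 436 against 18.1 CPM (4.59 ± 0.14) and Nrp1 at 366 CPM (5.18 ± 0.17). The interleukin-2 receptor chain Il2rb was at 845 against 113 CPM (2.90 ± 0.12), and Cish, a target of its signal, rose by 2.72 ± 0.13. Proliferation genes fell, with Mki67 at 88.6 against 287 CPM, Stmn1 at -2.67 ± 0.14 and Top2a at -2.29 ± 0.13. Ccr9, a receptor of thymocytes, fell from 468 to 32.0 CPM (-3.86 ± 0.13). Of 12419 genes 3803 passed, 1753 higher and 2050 lower. Which direction had more genes depended on the setting, with 1999 higher and 1656 lower with only these 2 groups, 2144 and 1829 with all 30 libraries, 1874 and 1820 with RLE factors, and 1010 and 761 among genes that differed at least 2-fold.

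Treg-associated genes were higher in 33 of 34 cases and lower in none. Of 18 genes that Treg cells reduce 13 were lower and 2 higher (13 and 3 adjusted over the list alone), among them Satb1 (-2.04 ± 0.09), Lef1 (-1.88 ± 0.10) and Tcf7 (-1.29 ± 0.09). NF-kB and tumour necrosis factor receptor genes were higher in 13 of 14 cases (Tnfrsf4 2.32 ± 0.14, Tnfrsf1b 2.17 ± 0.12). Of 15 interleukin-2 and STAT5 genes 9 were higher and 1 lower. The proliferation list had 23 lower and 1 higher of 25, and immature-thymocyte genes were lower in 9 of 12 and higher in none. Egress and maturation genes were higher in 8 of 14 and lower in 1 (Ifngr1 2.41 ± 0.12, S1pr1 1.15 ± 0.11; adjusted p = 0.126 with an estimated correlation). T-cell transcription factors had 11 lower and 8 higher of 27 (12 and 8 adjusted over the list alone), with a median below 0, a mean above 0 and fry's direction below 0. Of 16 chromatin architecture genes 2 were lower, Hcfc1 (-0.65 ± 0.09) and Trim28 (-0.47 ± 0.10), and none higher. Ccr6 was at 96.3 against 1.56 CPM and Ttn at 212 against 0.363 CPM. Iglon5 was at least 80.6-fold, Vsig10 at least 36.8-fold, Actg2 at least 36.4-fold and Cd80 at least 30.5-fold higher, and Cacng4 at least 19.6-fold and Akr1c18 at least 17.6-fold lower. Slc15a1 fell by 5.70 ± 0.50.

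CD25+ reporter-low cells against conventional CD4 cells give the full Treg contrast in thymus. Il2ra was at 1090 against 12.1 CPM (6.49 ± 0.14, n = 2 per group, adjusted p = 4.86e-34 by edgeR) and Foxp3 at 889 against 2.16 CPM (8.67 ± 0.20). Il2rb reached 1240 against 113 CPM (3.46 ± 0.12), Ctla4 535 against 18.1 CPM (4.89 ± 0.14) and the costimulatory receptor Tnfrsf4 695 against 97.9 CPM (2.84 ± 0.14). Satb1, a genome organiser, fell from 2530 to 442 CPM (-2.51 ± 0.09), Tcf7 from 2560 to 764 CPM (-1.73 ± 0.09) and Pde3b, a gene that Foxp3 represses, from 149 to 5.25 CPM (-4.80 ± 0.20). The chemokine receptor Ccr6 was at 172 against 1.56 CPM (6.76 ± 0.28) and Cd83 at 164 against 1.95 CPM (6.40 ± 0.28). A total of 3728 of 12419 genes passed, 1975 higher and 1753 lower, and of those that differed at least 2-fold 1149 were higher and 592 lower.

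All but 1 of 34 Treg-associated genes were higher, none was lower, and of 18 genes that Treg cells reduce 13 were lower and 1 higher. NF-kB and tumour necrosis factor receptor genes were higher in 13 of 14 cases and interleukin-2 and STAT5 genes in 11 of 15 with 1 lower (12 and 1 adjusted over the list alone). TCR-signalling genes had 10 higher and 5 lower of 22 (11 and 7 adjusted over the list alone; camera adjusted p = 0.0773). Immature-thymocyte genes were lower in 11 of 12. Proliferation genes had 13 lower and 2 higher of 25 (16 and 2 adjusted over the list alone), with Stmn1 at -1.41 ± 0.12, Mcm6 at 0.81 ± 0.10 and an adjusted p = 0.394 with an estimated correlation. The list of T-cell transcription factors had 14 lower and 8 higher of 27 (16 and 8 adjusted over the list alone), with a median below 0, a mean above 0 and an adjusted p = 0.25 with an estimated correlation. Of 16 chromatin architecture genes 3 were lower (Hcfc1 -0.54 ± 0.09) and none higher, 2 and none adjusted over the list alone. Iglon5 was at least 66.0-fold, Ptrf at least 48.7-fold, Kcnj15 at least 44.7-fold, Cd80 at least 40.8-fold and Actg2 at least 37.1-fold higher, and Adamts14 at least 47.9-fold, Klrb1c at least 42.4-fold and Adamts3 at least 16.5-fold lower.

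CD25+ reporter-low cells against CD25+ reporter-negative cells ask what accompanies Foxp3 once CD25 is present. Differences may also come from CD4-CD8- cells mixed into the reporter-negative libraries, which could not be told apart. Foxp3 differed by 3.97 ± 0.13 (889 against 63.0 CPM, n = 2 per group, adjusted p = 1.22e-26 by edgeR) and Il2ra by 0.87 ± 0.10. Itgae, an integrin of Treg cells, was at 347 against 14.1 CPM (4.77 ± 0.18), Ikzf4 at 586 against 142 CPM (2.20 ± 0.12) and Il2rb at 1240 against 241 CPM (2.51 ± 0.11). S1pr1 rose by 1.82 ± 0.12 and the homing receptor Sell by 1.62 ± 0.10. Of 12 immature-thymocyte genes 9 were lower and 2 higher. Ptcra and others of less mature cells fell, with Ptcra at 1.24 against 65.0 CPM (-5.54 ± 0.31), Arpp21 at 8.47 against 305 CPM (-5.01 ± 0.15) and Notch1 at -1.55 ± 0.10. In this pair 4826 of 12419 genes passed, 2500 higher and 2326 lower.

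Every one of 15 interleukin-2 and STAT5 genes was higher (Pim1 2.33 ± 0.14, Cish 1.80 ± 0.12), as was every one of 14 egress and maturation genes. Treg-associated genes were higher in 33 of 34 cases. Genes that Treg cells reduce had 9 lower and 5 higher of 18, with Pde3b at 5.25 against 69.9 CPM, Tcf7 at -1.31 ± 0.09 and Il7r higher by 1.49 ± 0.13 (adjusted p = 0.204 with an estimated correlation). NF-kB and tumour necrosis factor receptor genes were higher in 12 of 14 (Traf1 2.16 ± 0.13; adjusted p = 0.0615 with an estimated correlation), and TCR-signalling genes in 13 of 22 with 2 lower (Pdcd1 1.65 ± 0.15; adjusted p = 0.24 with an estimated correlation). Proliferation genes were lower in 24 of 25 and higher in none, and early CD4-CD8- genes lower in 11 of 19 and higher in 4. Interferon-response genes were higher in 17 of 22 and lower in 1, among them Gbp3 (2.83 log2) and Stat1 (1.08 ± 0.10), with an adjusted p = 0.196 with an estimated correlation. The CD4-lineage list had 5 higher and 3 lower of 8, with a median above 0 and a mean below 0. Klrg1 was at least 22.2-fold higher and Il1rl1 stood at 79.1 against 0.278 CPM. Odz1 was at least 79.2-fold, Atoh8 at least 23.3-fold, Esm1 at least 22.4-fold and Muc13 at least 17.7-fold lower, and Slc5a9 was at 0.313 against 66.0 CPM.

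CD25+ reporter-low cells against CD25- reporter-positive cells compare the 2 gates with high Foxp3. Il2ra rose by 1.26 ± 0.10 (1090 against 455 CPM, n = 2 per group, adjusted p = 2.23e-12 by edgeR), while Foxp3 was not called (0.17 ± 0.11, adjusted p = 0.42). Of the proliferation genes, Mcm5 was at 116 against 43.2 CPM (1.43 ± 0.13), Mki67 at 196 against 88.6 CPM (1.15 ± 0.12) and Top2a up by 1.28 ± 0.14, while the list had an adjusted p = 0.051 with an estimated correlation. Pde3b stood at 5.25 against 32.3 CPM (-2.59 ± 0.23), and Satb1 fell by 0.47 ± 0.08. Genes passing numbered 860 of 12419, 627 higher and 233 lower. The share higher, 72.9%, was 52.7% with all 30 libraries in 1 fit, 58.6% with only these 2 groups and 58.8% without the CD25+ reporter-negative and CD8 libraries. With the same libraries it was 65.8% with RLE factors, 63.3% with the stricter filter and 65.1% with DESeq2, so the share depended on the setting and the cause was not isolated. Without CD25- reporter-positive replicate 2 the count was 408, and without CD25+ reporter-low replicate 1 or replicate 2 it was 397 or 439.

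Of 25 proliferation genes 19 were higher and none lower (23 and none adjusted over the list alone; adjusted p = 0.051 with an estimated correlation). Treg-associated genes had 14 higher, 1 lower and 19 not called of 34 (17 and 3 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation), among them Gpr83 at 312 against 143 CPM (1.14 ± 0.15). Genes that Treg cells reduce had 6 lower and none higher of 18 (8 lower and 2 higher adjusted over the list alone; adjusted p = 0.0556 with an estimated correlation). Interleukin-2 and STAT5 genes had 6 higher and none lower of 15 (7 higher adjusted over the list alone; Socs2 1.36 ± 0.27; adjusted p = 0.172 with an estimated correlation). Of 22 interferon-response genes 3 were lower (7 adjusted over the list alone), including Rsad2 (-1.37 ± 0.32), with an adjusted p = 0.448 with an estimated correlation. The largest rises were Ptrf (4.13 ± 0.63), Kcnj15 (3.64 ± 0.61), Kif4 (3.10 ± 0.54), Pask (2.98 ± 0.45), Mxd3 (2.98 ± 0.52) and the mitotic kinase Cdk1 (7.97 against 1.13 CPM). The largest falls after Pde3b were Car2 (-2.17 ± 0.64), Hs3st3b1 (-2.14 ± 0.59), Zfp69 (-2.13 ± 0.56), Cybb (3.07 against 13.4 CPM) and Fam101b (-2.07 ± 0.34). Without CD25- reporter-positive replicate 2 the calls of Car2 (-2.29), Hs3st3b1 (-0.85), Zfp69 (-1.43), Cybb (-1.61), Rsad2 (-1.28) and Socs2 (1.12) were lost. Calls were also lost without CD25+ reporter-low replicate 1 for Car2 (-2.03), Hs3st3b1 (-2.0), Zfp69 (-1.79) and Rsad2 (-1.38), without replicate 2 for Car2 (-2.34), Hs3st3b1 (-2.31) and Rsad2 (-1.36), and without CD25- reporter-positive replicate 1 for Car2 (-2.03).

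Spleen Treg against Tcon cells give the same contrast in a peripheral organ. Il2ra was at 824 against 1.53 CPM (9.0 ± 0.13, n = 3 per group, adjusted p = 2.41e-45 by edgeR) and Foxp3 at 499 against 1.2 CPM (8.56 ± 0.15). Lrrc32, which presents latent TGF-beta on Treg cells, was at 368 against 0 CPM, at least 1740-fold higher, and the transcription factor Ikzf2 at 797 against 4.81 CPM (7.30 ± 0.11). Pde3b fell from 177 to 6.64 CPM (-4.80 ± 0.14), Igfbp4 fell by 2.23 ± 0.07 and Il7r, the interleukin-7 receptor, fell by 1.45 ± 0.07. The chemokine receptors Ccr6 and Cxcr5 rose, the former to 34.4 from 0.0591 CPM and the latter by 4.58. Mki67 was at 87.5 against 8.10 CPM (3.40 ± 0.16). Of 10694 genes 3489 passed, 1920 higher and 1569 lower, and of those that differed at least 2-fold 951 were higher and 294 lower. Tcon replicate 2 stood apart, with 26% of its reads in no feature against 15.8% and 16.4% in the other Tcon libraries, and without it 3114 genes passed.

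All 35 Treg-associated genes were higher. Genes that Treg cells reduce had 14 lower and 2 higher of 17 (15 and 2 adjusted over the list alone). All 14 NF-kB and tumour necrosis factor receptor genes (Tnfrsf4 4.51 ± 0.12) and all 10 helper-cytokine and effector genes were higher, the latter including Cxcr3 (6.43 log2). Proliferation genes were higher in 16 of 22 and lower in none (18 and none adjusted over the list alone). Egress and maturation genes were lower in 10 of 14 and higher in 2. CD8-lineage genes had 5 higher and 4 lower of 10 (5 each adjusted over the list alone), with a median below 0, a mean above 0 and fry's direction below 0. Of 16 chromatin architecture genes 3 were lower and none higher (Smchd1 -0.48 ± 0.08; adjusted p = 0.205 with an estimated correlation). Serpina3g was at least 455-fold, Socs2 at least 305-fold, Naip6 at least 223-fold and Klrg1 at least 119-fold higher. Pdlim4 (-6.59 ± 0.28), Ggt5 (-6.07 ± 0.24), Lypd6b (-5.70 ± 0.31) and Atp8b4 (-5.36 ± 0.22) fell the most. Some genes of the B-cell and myeloid lists were also higher in Treg libraries, with Cd79b at 15.7 against 0.367 CPM and Cybb at 44.2 against 0.505 CPM. Cd19, another B-cell gene, had at most 2 counts in any spleen library, so Cd79b by itself does not show B cells.

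The contrast of Treg with conventional cells was tested for a difference between spleen and thymus, with CD25+ reporter-low and conventional CD4 cells as the thymic pair. No library batch is given in the labels used here, so an effect of tissue cannot be told apart from one of batch. Of 11645 genes 2041 differed, 1113 with a more positive effect in spleen and 928 with a less positive one. The Foxp3 effect was not shown to differ (-0.12 ± 0.44, adjusted p = 0.921 by edgeR; 0.30 without spleen Tcon replicate 1), whereas those of Il2ra (2.5 ± 0.23), Ikzf2 (4.04 ± 0.16), Il2rb (1.66 ± 0.12) and Itgae (4.64 ± 0.36) were more positive in spleen. For all 4 genes the comparison cells differed, with 1.53, 4.81, 32.5 and 0.407 CPM in spleen Tcon against 12.1, 120, 113 and 19.7 CPM in conventional CD4 thymocytes. The Treg means were lower in spleen, at 824, 797, 1160 and 203 CPM against 1090, 1140, 1240 and 347 CPM. Mki67 differed by 3.94 ± 0.18 and Ccr9 by 6.83 ± 0.22, the latter at 468 CPM in conventional CD4 thymocytes and 3.93 CPM in spleen Tcon. Mki67 was at 87.5 and 8.10 CPM in spleen Treg and Tcon and at 196 and 287 CPM in the thymic pair. Egress genes had a lower effect in spleen, with Sell at -1.85 ± 0.10. Sell was at 963 and 993 CPM in spleen and thymic Treg cells, and at 1120 and 332 CPM in their comparison cells. Its difference thus lay mostly in the comparison cells.

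Of 35 Treg-associated genes 18 had a more positive effect in spleen, 3 a less positive one and 14 were not called (20 and 4 adjusted over the list alone). None of 14 egress and maturation genes was more positive and 11 were less so (1 and 11 adjusted over the list alone). Proliferation genes were more positive in 16 of 25 and less in none (19 and none adjusted over the list alone), and immature-thymocyte genes more in 7 of 12 and less in 1. For 14 NF-kB and tumour necrosis factor receptor genes, 2 went each way (2 more and 4 less positive adjusted over the list alone), with a median below 0 and a mean above 0. Among 16 chromatin architecture genes 1 differed, Hcfc1 (0.42 log2). Asb2 was at 30.2 and 0.0591 CPM in spleen Treg and Tcon and at 3.14 and 36.7 CPM in the thymic pair. Klrb1c, Mmp9 and Gzmb likewise stood higher in Treg cells in spleen and in conventional cells in thymus, with Klrb1c at 1.95 and 0.0773 CPM and at 0 and 13.0 CPM. Fam46a ran opposite (-5.52 ± 0.27), at 19.8 and 46.5 CPM in spleen and 101 and 5.30 CPM in thymus.

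Genes that differed at least 2-fold in spleen served as Treg sets for the thymic contrasts. Of the 936 spleen-higher genes that were measured, 599 were higher and 98 lower in CD25- reporter-positive cells against conventional CD4 cells, 655 and 66 in CD25+ reporter-low cells and 424 and 68 in CD25+ reporter-negative cells. Of the 282 spleen-lower genes, 145, 169 and 146 were lower in those contrasts and 15, 8 and 16 higher. In CD25+ reporter-low against CD25- reporter-positive cells 177 of the spleen-higher genes were higher and 19 lower. The 3 contrasts share their conventional CD4 libraries, so their counts are not independent.

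Foxp3 knockout against GFP wild-type Treg cells ask what the allele labelled knockout changes in cells that still transcribe the locus; no value here measured Foxp3 protein. Foxp3 transcript was detected in both libraries labelled knockout, at 309 and 329 CPM against 569 and 562 CPM (-0.80 ± 0.09, n = 2 per group, adjusted p = 3.86e-08 by edgeR). Il2ra fell from 738 to 278 CPM (-1.38 ± 0.08), Itgae from 271 to 26.9 CPM (-3.30 ± 0.13) and Lrrc32 from 550 to 137 CPM (-1.98 ± 0.10). Pde3b rose from 5.45 to 60.7 CPM (3.52 ± 0.22) and Tcf7, a factor of conventional T cells, from 762 to 1910 CPM (1.35 ± 0.07). Rorc, the regulator of interleukin-17-producing cells, rose from 6.57 to 67.4 CPM (3.37 ± 0.26), and the cytokine Il17a and the chemokine Ccl20 stood at 5.44 and 6.97 CPM in the knockout, with Il17a at 0.0827 CPM in the wild type. Of 12405 genes 1570 passed, 668 higher and 902 lower, and the count was 947 without knockout replicate 1 and 1013 without knockout replicate 2.

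Of 35 Treg-associated genes 31 were lower, 1 higher and 3 not called, among them Nrp1 (-1.78 ± 0.09) and Tnfrsf4 (-1.76 ± 0.09). Genes that Treg cells reduce were higher in 15 of 19 and lower in none (18 and none adjusted over the list alone), including Igfbp4 (1.42 log2) and Actn1 (1.22 log2). Of 14 NF-kB and tumour necrosis factor receptor genes 11 were lower and none higher (12 lower adjusted over the list alone), and of 15 interleukin-2 and STAT5 genes 5 were lower and none higher (Il2rb -1.24 ± 0.09). Helper-cytokine and effector genes went both ways, 6 higher and 4 lower of 16 (8 and 5 adjusted over the list alone; camera adjusted p = 0.603), with Gzmb at 106 against 418 CPM and Cxcr5 at -2.08. Interferon-response genes were lower in 16 of 22 and higher in none (17 lower adjusted over the list alone; Oas1a -1.81 ± 0.21). None of 16 chromatin architecture genes was called, by edgeR or DESeq2, with 2 at an unadjusted p under 0.05 by edgeR; the nearest was Smc1a (0.29 ± 0.11, adjusted p = 0.0953), which was called with no filter on low counts (adjusted p = 0.0322) and without GFP wild-type replicate 2 (0.44, adjusted p = 0.0216). Proliferation genes had 5 higher and 2 lower of 25 (9 and 2 adjusted over the list alone; Top2a 0.75 log2; adjusted p = 0.123 with an estimated correlation). CD8-lineage genes had 3 higher and 3 lower of 12 (4 and 3 adjusted over the list alone), with a median and a mean above 0 and fry's direction below 0. The largest falls were Slc15a2 (0.435 against 58.3 CPM, -6.98 ± 0.40), Fam160a1 (-4.23 ± 0.57), Lad1 (-3.91 ± 0.36) and Mmp9, and the largest rises Qrfp, Mstn and Pls3, each under 0.4 CPM in the wild type. Of 11 dissociation-stress genes 5 were lower (6 adjusted over the list alone; Fos -0.70 ± 0.09; adjusted p = 0.0759 with an estimated correlation), and the plasma-cell transcript Igkc rose by 1.76 ± 0.15.

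DSM mutant against DSM wild-type Treg cells ask what the domain-swap mutation changes while Foxp3 is still transcribed. The domain swap is an exchange of parts between a pair of Foxp3 forkhead domains, and no value here measured DNA binding. Foxp3 was at 446, 487 and 418 CPM in the mutant and at 569, 519 and 500 CPM in the wild type (-0.18 ± 0.07, n = 3 per group, adjusted p = 0.133 by edgeR; -0.25 and 0.0216 without mutant replicate 2), and Il2ra was not called (-0.15 ± 0.07, adjusted p = 0.211). Pde3b rose from 4.78 to 27.6 CPM (2.58 ± 0.18) and Vipr1 from 22.4 to 99.1 CPM (2.20 ± 0.11). Tigit, an inhibitory receptor, fell from 129 to 52.4 CPM (-1.25 ± 0.09), and the chemokine receptors Cxcr5 (-1.32 ± 0.12) and Cxcr3 (-1.12 ± 0.12) fell too. Genes passing numbered 762 of 12405, 354 higher and 408 lower, and of those that differed at least 2-fold 31 were higher and 126 lower. Without mutant replicate 1 the count was 1197, without mutant replicate 3 it was 430, and without wild-type replicate 1, 2 or 3 it was 375, 433 or 504.

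Of 35 Treg-associated genes 15 were lower, 4 higher and 16 not called (22 lower and 4 higher adjusted over the list alone), among them Tnfrsf9 (-0.68 ± 0.09) and Icos (-0.58 log2). Genes that Treg cells reduce were higher in 9 of 19 and lower in none (12 higher adjusted over the list alone), including Igfbp4 (0.79 ± 0.07) and Actn1 (0.60 ± 0.07). NF-kB and tumour necrosis factor receptor genes were lower in 8 of 14 and higher in none (11 lower adjusted over the list alone; Tnfrsf1b -0.74 ± 0.08; adjusted p = 0.0759 with an estimated correlation). Of 14 egress and maturation genes 5 were higher (S1pr1 0.56 log2; adjusted p = 0.0944 with an estimated correlation). Of 16 chromatin architecture genes 1 was higher, Rad21 (0.27 ± 0.08, adjusted p = 0.0482), and the list had an adjusted p = 0.38 with an estimated correlation. The Rad21 call was lost without mutant replicate 2 (0.21), mutant replicate 3 (0.26) or wild-type replicate 1 (0.27), 2 (0.27) or 3 (0.28), and the adjusted p was 0.0702 with DESeq2, 0.0517 with RLE factors and 0.0504 with a replicate block. No proliferation gene of 25 was called by edgeR or DESeq2, and 6 had an unadjusted p under 0.05 by edgeR. Interferon-response genes had 1 lower of 22 (6 adjusted over the list alone; Oas1a -0.84 log2; adjusted p = 0.0759 with an estimated correlation). Besides Pde3b and Vipr1, Ggt5 (2.20 ± 0.36), Tspan9 (1.74 ± 0.34), Dapl1 (1.59 ± 0.25) and Slc15a2 (1.53 ± 0.17) rose the most; with all 30 libraries in 1 fit the Slc15a2 call was lost (1.53, adjusted p = 0.403). Slc24a3 (-2.91 ± 0.50), Tshz2 (-2.47 ± 0.40), Baiap3 (39.8 to 7.56 CPM), Sostdc1 (-2.25 ± 0.45), Ier5l (-2.13 ± 0.46) and Cebpa (-2.10 ± 0.30) fell the most, and the Ier5l call was lost without wild-type replicate 1 (-1.89). The stress gene Hspa1b was at 706 against 312 CPM (1.23 ± 0.07). Ighm, of the B-cell list, was at 349 against 831 CPM (-1.20 ± 0.10). Cd19, another B-cell gene, was at most 0.277 CPM in these libraries, so Ighm by itself does not show B cells. Of 11 dissociation-stress genes 6 were higher and 2 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.128 with an estimated correlation).

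**Figure D2:**
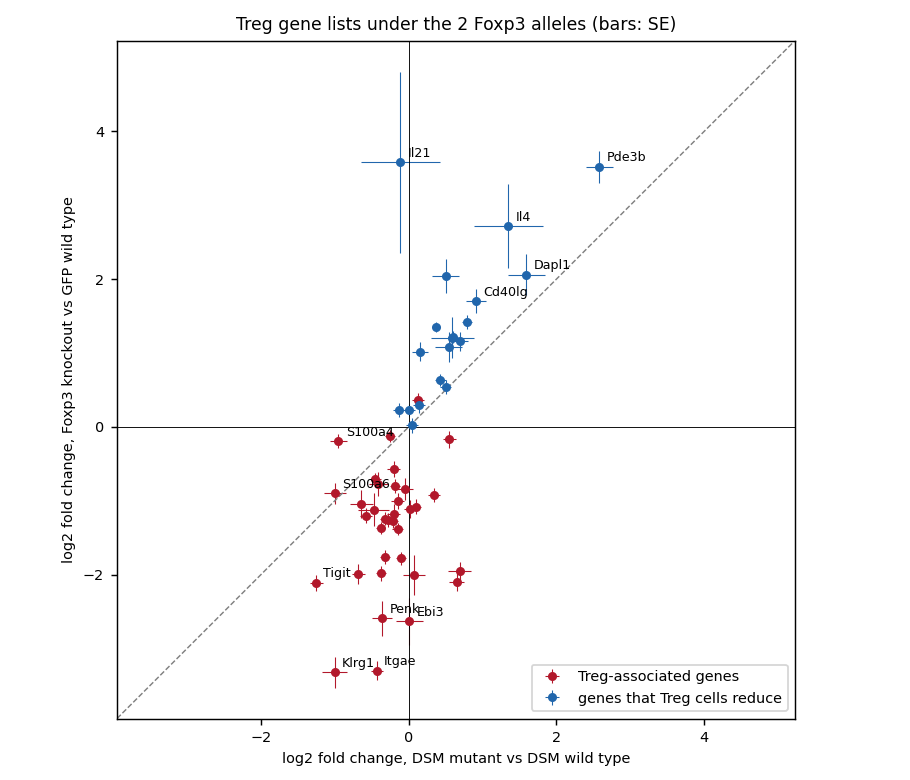
Log2 fold change of the Treg-associated genes and the genes that Treg cells reduce, in DSM mutant against wild type (x axis) and Foxp3 knockout against GFP wild type (y axis); bars are SE and the dashed line marks equal change. Itgae lies at -3.30 in the knockout, and Pde3b at 2.58 in the mutant and 3.52 in the knockout.

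The Foxp3 alleles were then compared with each other, each against its own wild type. Among these libraries Ddx3y, a gene of the Y chromosome, was detected only in the DSM mutant and its wild type. The sex-linked pattern thus split the libraries by set, DSM or knockout, and not by mutant against wild type within a set. A difference between the DSM and knockout effects cannot be told apart from this pattern. Of 12405 genes 227 were lower in both contrasts where 29.7 would be by independence (Fisher's exact test, 2-sided, p = 5.58e-156), 156 were higher in both where 19.1 would be (p = 2.34e-106), and of the 418 called in both 17 and 18 went opposite ways. Over the 762 genes called in the DSM contrast, 82.8% had the same sign in the knockout, and the correlation across genes was 0.448. It was 0.332 over the 1570 genes called in the knockout contrast, where the slope of DSM on knockout change was 0.119, and 0.179 over all genes tested, with genes not being independent replicates. Of the 951 spleen-higher Treg genes, 418 were lower and 47 higher in the knockout, and 197 were lower and 20 higher in the DSM mutant. Of 286 spleen-lower genes 100 were higher and 6 lower in the knockout, and 46 and 4 in the mutant.

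The knockout effect minus the DSM effect was tested gene by gene, and 485 of 12405 genes differed, 206 with a more positive and 279 with a more negative effect in the knockout. The count was 319 without knockout replicate 1. The effect in the knockout was more negative for Il2ra (-1.23 ± 0.11), Foxp3 (-0.61 ± 0.11), Itgae (-2.87 ± 0.15), Il1rl1 (-2.75 ± 0.15), Nrp1 (-1.68 ± 0.11) and Gzmb (-2.64 ± 0.20). Of these, Il1rl1 (57.5 against 38.0 CPM) and Gzmb (14.6 against 9.14 CPM) averaged higher in the mutant than in its wild type. It was more positive for Rorc (3.79 ± 0.34), the homing receptor Ccr6 (2.13 ± 0.27) and Tcf7 (0.98 ± 0.10), although Rorc (9.36 against 12.9 CPM) and Ccr6 (23.1 against 36.2 CPM) averaged lower in the mutant. Slc15a2 had the largest negative difference with an adjusted p under 0.05 (-8.51 ± 0.43) and fell in the knockout while it rose in the mutant. Lad1 differed by -4.27 ± 0.39 and Eps8l1 by 5.54 ± 0.57, and for Eps8l1 the wild types themselves stood at 0.197 CPM with GFP and 43.0 CPM in the DSM set. With all 30 libraries in 1 fit the calls of Slc15a2 (-8.49, adjusted p = 0.052) and Eps8l1 (5.50, adjusted p = 0.402) were lost.

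Of 35 Treg-associated genes 26 had a more negative effect in the knockout, 1 a more positive one and 8 were not called (29 and 1 adjusted over the list alone), and of 19 genes that Treg cells reduce 6 were more positive and none more negative (10 and none adjusted over the list alone). Of 22 interferon-response genes 7 were more negative and none more positive (9 and none adjusted over the list alone). None of 16 chromatin architecture genes differed by edgeR or DESeq2, and 0 had an unadjusted p under 0.05; the nearest was Trim28 with an adjusted p = 0.421. Of 11 dissociation-stress genes 6 were more negative (8 adjusted over the list alone; Hspa1b -2.29 ± 0.16), and of 7 erythroid genes 4 were more negative. Each allele had its own control group, so a difference between the control libraries adds to these values.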

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

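The tests of the patterns below were chosen after the result was seen, except those on cells returned to the thymus, on mature CD8 cells and on other splits of the samples.

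Effects that differed between a pair of contrasts drew attention first. The Foxp3 knockout and DSM effects differed for 485 genes, among them Slc15a2 (-8.51), Lad1 (-4.27), Itgae (-2.87), Il1rl1 (-2.75), Gzmb (-2.64), Hspa1b (-2.29), Nrp1 (-1.68), Il2ra (-1.23) and Foxp3 (-0.61), more negative in the knockout, and Eps8l1 (5.54), Rorc (3.79), Ccr6 (2.13) and Tcf7 (0.98), more positive, all on the log2 scale. The Treg effect differed between spleen and thymus for 2041 genes. It was more positive in spleen for Klrb1c (13.21), Asb2 (11.77), Mmp9 (10.23), Gzmb (8.32), Ccr9 (6.83), Itgae (4.64), Ikzf2 (4.04), Mki67 (3.94), Il2ra (2.5), Il2rb (1.66) and Hcfc1 (0.42), and less positive for Fam46a (-5.52) and Sell (-1.85). Klrb1c, Mmp9 and Gzmb had no counts in at least 1 group, so their fitted values are set by the prior count and their size is neither an estimate nor a bound.

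Treg libraries of the Foxp3-allele groups are labelled thymus but resembled splenic Treg cells. On an axis from thymic CD25+ reporter-low cells (0) to splenic Treg cells (1), the median position of 131 genes was 0.98 or more in each of the 4 groups, against 0.21 for CD25- reporter-positive thymocytes, which may reflect a spleen or other peripheral origin. A difference between library batches in newly made thymic Treg cells is argued against by 8 genes that splenic Treg cells lack, whose median stayed at or below 0.029 of the thymic level in each group. Rag1, which newly made T cells still carry, had 4 counts in 68331459 in these 10 libraries and 158 in 16891253 in the 4 thymic reporter-sorted libraries. Treg cells that had returned to the thymus cannot be told apart from splenic ones by this value, since no library holds resident and returned cells sorted apart.

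Genes of CD4-CD8- thymocytes were abundant in the CD25+ reporter-negative libraries, with Ptcra at 65.0 CPM. CD4+CD8+ cells mixed in are argued against by Cd8a at 1.65% and Cd8b1 at 7.05% of the CD4+CD8+ level beside Rag1 at 25.5%. A less mature CD4 stage just past CD4+CD8+ is argued against by 24 genes that CD4+CD8+ cells lack, whose median stood at 0.548 of the CD4-CD8- level, with 17 of them at 0.2 or more and the rest genes of neutrophils such as Ltf. CD25+ CD4-CD8- cells mixed in could lower the 31 genes that such cells lack, whose median was 0.382 of the conventional CD4 level. The same 31 genes stood at 0.459 and 0.453 in the reporter-positive and reporter-low gates, so they cannot decide. In the CD25+ reporter-low gate the 24 genes above had a median of 0.022 of the CD4-CD8- level, with 1 at 0.2 or more. For these 24 genes this argues against a change shared by all CD25+ cells. Mixing cannot be told apart from a change particular to the CD25+ reporter-negative cells. The sort on CD4 was meant to remove CD4-CD8- cells, but no value here measured its purity.

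The CD8 libraries carried genes of the cell cycle and of cells before selection. CD4+CD8+ cells mixed in are argued against by Cd4 at 4.9% of the CD4+CD8+ level while the proliferation list stood at a median ratio of 1.218. Mature CD8 thymocytes as the main population are argued against by the egress and maturation list, at a median of 0.162 of the conventional CD4 level. Immature CD8 single-positive cells, the stage before CD4+CD8+, are a candidate explanation. On an axis from CD4+CD8+ (0) to conventional CD4 cells (1), 131 genes had a median position of -0.064. These genes were chosen as higher in conventional CD4 than in CD4+CD8+ and CD4-CD8- cells. They can include CD4-lineage genes such as Zbtb7b, so their low position does not set immature CD8 cells apart from mature ones. No library of immature CD8 cells sorted apart was made, so the immature stage stays a hypothesis.

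The contrasts with 3 libraries per group were also computed for the other splits of the same 6 libraries. For the DSM mutant 1 of 10 splits, the real one, gave as many as 762 genes, and the highest of the others gave 0 by edgeR, with 989 at an unadjusted p under 0.05 against 2274. In spleen 1 of 10 splits, again the real one, gave 3489 genes and the highest other 0, with 204 against 4320 unadjusted. DESeq2 was not run on the splits, and 10 splits are too few for a share under 0.05. Every other split also put libraries of both real groups on each side, so the real difference added to the spread. The counts of 0 are therefore no measure of chance.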

How the results depend on the processing

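The fits added after seeing the data are those without the CD25+ reporter-negative and CD8 libraries and the one with the CD25- reporter-positive group as thymic Treg cells. Of 312 values of named genes, 305 were called, and 297 kept their direction and their side of the threshold in every alternative that gave a value. The 2-fold rule was not applied to these values, and DESeq2 gave no adjusted p for a few of them. Apart from Foxp3, Il2ra, Cd4 and Cd8a, the named genes were picked from the same data for large changes or low adjusted p. Their stability therefore does not stand for all called genes. Of the 762 DSM calls, 48.3% were kept without wild-type replicate 1 and 90.6% without mutant replicate 1. In spleen 82.5% were kept without Treg replicate 1 and 89.9% without Treg replicate 2. Counts of called genes stayed within 1.5 times under RLE factors, no filter, the stricter filter, DESeq2, all 30 libraries in 1 fit, only the groups compared and the added fits. Which direction had more genes was not stable in 6 contrasts: CD4+CD8+ against CD4-CD8-, conventional CD4 against CD4+CD8+, CD8, CD25+ reporter-negative and CD25- reporter-positive against conventional CD4, and the DSM mutant (645 higher and 552 lower without mutant replicate 1). Asking for at least 2-fold reduced each count, as a stricter rule must: 1711 (691 higher and 1020 lower) for CD4+CD8+ against CD4-CD8- cells, 2661 (1231 and 1430) for conventional CD4 against CD4+CD8+ and 4158 (2091 and 2067) for CD8 against conventional CD4. Against conventional CD4 it left 1764 (1167 and 597) for CD25+ reporter-negative, 1771 (1010 and 761) for CD25- reporter-positive and 1741 (1149 and 592) for CD25+ reporter-low cells. It gave 2185 (1103 and 1082) and 275 (238 and 37) for CD25+ reporter-low against CD25+ reporter-negative and CD25- reporter-positive cells, 1245 (951 and 294) for spleen, 626 (244 and 382) for the knockout and 157 (31 and 126) for the DSM mutant. For the difference of the Foxp3 alleles it gave 246 (113 more positive and 133 more negative) and for that of spleen and thymus 885 (566 and 319). Leaving out 1 library gave 397 to 582 for CD25+ reporter-low against CD25- reporter-positive cells, 947 to 1270 for the knockout, 375 to 1197 for the DSM mutant and 319 to 567 for the difference of the alleles, with fewer libraries fitted. The rise to 1197 was without DSM mutant replicate 1, and the cause was not tested. An estimated correlation left 68 of 154 camera calls on lists and all 20 on spleen-defined sets. At an unadjusted p in both, 912 genes changed the same way under both Foxp3 alleles, against 383.

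With a replicate block the counts were 4286, 5316, 7305, 4508, 3975, 3908, 4969, 990, 3374, 1575, 826, 484 and 2005, in the order given for the 2-fold rule. Between libraries of different thymocyte groups with the same replicate number, the correlation of residuals across genes ran from -0.045 to 0.144, with a median of 0.058. It was above 0.1 in 3 of 21 pairs of groups (with 2 libraries per group both numbers give the same value). In spleen, pairs with the same number ran from 0.022 to 0.098 and other pairs from -0.068 to 0.007. The value was -0.007 in the knockout set, with a median of 0.001 in the DSM set. A weak link by number is possible in thymocytes and spleen. The labels do not say that a number links libraries, so no pairing was assumed. Of the 4 values of Foxp3 that were not called, 2 changed sign: leaving out 1 library gave -0.66 to 2.16 in conventional CD4 against CD4+CD8+ cells (each extreme without 1 CD4+CD8+ replicate) and -0.46 to 0.30 in the difference of spleen and thymus (the latter without spleen Tcon replicate 1), which was 0.01 with CD25- reporter-positive cells; the cause was not tested. At 3065421 to 9504930 counts in genes and 2 or 3 libraries per group, simulated 1.5-fold changes were recovered in 22.7% to 59.4% of cases. The simulations changed fewer genes than the contrasts called, which affects the adjusted p. Changes of that size may be missed, but the share missed in the real contrasts was not measured.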

Other observations

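Genes of interleukin-2 and STAT5 signalling went both ways at the step from CD4-CD8- to CD4+CD8+ cells. Of 15, 8 were lower, 3 higher and 4 not called, with Il2rb at 21.1 against 111 CPM (-2.37 ± 0.15) and Cish, a feedback inhibitor of cytokine signals, at 4.77 against 44.1 CPM (-3.14 ± 0.22); the list had an adjusted p = 0.143 with an estimated correlation. In conventional CD4 against CD4+CD8+ cells, 19 of 34 Treg-associated genes were higher and 5 lower (adjusted p = 0.0631 with an estimated correlation), and of 18 genes that Treg cells reduce 13 were higher and 2 lower (14 and 2 adjusted over the list alone). In CD25- reporter-positive cells the chemokine receptors Cxcr3 (3.20 log2) and Cxcr5 (3.95 log2) were higher than in conventional CD4 cells.

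In the wild-type Treg libraries with the GFP reporter, Gzmb, a granule protease, stood at 418 CPM and the receptor Klrg1 at 89.0 CPM. Spleen Treg libraries had 6.39 and 26.9 CPM of these, and DSM wild-type libraries 9.14 and 19.6 CPM. The Foxp3 wild types were thus not alike, and no test was made between them, since genotype and library set are the same split.

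Transcripts that differ between the sexes split the libraries by set. The 6 DSM libraries had Xist at 0.268 to 0.692 CPM and Ddx3y, a gene of the Y chromosome, at 140 to 224 CPM. All other libraries had Xist at 1320 to 4560 CPM and no Ddx3y, except 1 CD25+ reporter-low library with 0.772 CPM. The labels give no sex, and both genotypes of the DSM contrast had the same pattern, as did both of the knockout contrast. The pattern differed between the DSM and knockout contrasts, so a comparison of their effects cannot be separated from it.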
